A study of Triticum aestivum with 34 samples.

How the data were processed

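RNA sequencing was done on wheat (Triticum aestivum, genotype shimai22, untreated) spikelets, the units of the wheat ear that hold the florets. Basal spikelets and central spikelets of the ear were taken on days 6, 9 and 12 and again on days 15, 21 and 27 after the terminal spikelet stage, the stage at which the ear has formed its last spikelet. The labels gave 34 libraries in 12 groups of position and day. Each group had 3 libraries, except basal day 15 and central day 21, which had 2. Total RNA was extracted with Trizol, samples with a RIN (RNA integrity number) above 7 were used, and libraries were made by an Illumina protocol, per the labels. How many plants were pooled in a library, and whether replicates came from separate plants, was not stated.

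The deposited values were in 1 table of 162233 gene models. Per the file headers and their values, the authors gave each library a column of estimated counts, which were whole numbers with no normalization, and a column of FPKM, in which the authors had scaled the fragments for transcript length and library total. The table also gave each model's position, gene name and description. The submitters' processing notes named Bowtie 0.12.2 and the builds mm8 and mm9, which are mouse builds and so are not the genome of these values. The aligner, the counting tool, its strand setting and the wheat build were not given in the sources used here. Of 54078 high-confidence gene models, 79.3% overlapped a protein-coding gene of the RefSeq annotation of the Chinese Spring assembly of the wheat genome consortium (RefSeq v2.1), against 6.3% after a shift of 5 Mb. Coordinates below are therefore given in that build. The model names came from a transcript assembly merged with the annotation. Among the tested models, 975 joined 2 or more annotated genes, 1453 had no annotated gene name, 6760 had no description and 19.6% were of the low-confidence class.

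The small estimated counts piled up at multiples of 4, with 33.9 to 35.6% of them there per library against 25% if spread evenly. Most small counts were not multiples of 4. One reading of this excess, not tested, is that a sequenced fragment was often worth about 4 counts. Totals were 95144712 to 126139684 counts per library, and the number of fragments behind a value was not given. The floor used for a group at 0 was therefore set at 12 counts per library, which is 3 fragments if a fragment was worth 4 counts, and a fold against such a group was written as a lower bound. Floors cover counting error only. Bread wheat carries 3 related subgenomes, so near-identical gene copies may share reads, and how shared reads were assigned was not given. Values of single copies carry that limit.

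The design had assumed FPKM values with limma as the test, and edgeR on counts if the table held counts; the second was used. Models with FPKM of at least 1 in at least 2 libraries were tested, which left 71963 models holding 98.86 to 99.21% of each library's counts. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 12 group means and bias-adjusted quasi-likelihood dispersions (glmQLFit with legacy = FALSE, then glmQLFTest). Contrasts were basal minus central at each day, their mean over 6 days, the steps between days as the mean of both positions, and an F test over 5 contrasts for a basal minus central difference that changed over days. Adjusted p-values are those of Benjamini and Hochberg over all tested models within a contrast, with 0.05 as the threshold and no fold threshold. Log2 differences are given with approximate standard errors (SE), taken back from the test as the absolute difference divided by the square root of its F value. Levels are FPKM as mean ± SD of a group.

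The test was run on simulated data with known changes in the day 6 contrast and in the mean of 6 days, over 71963 models each. Every simulated count was a multiple of 4, unlike most real small counts, and the spread was set by a formula and not fitted to the data. Changes were given only to models above a lower limit on mean count. The rates below hold for these settings and may differ in the real table. At day 6 it recovered 13.4% of 1.5-fold, 71.6% of 2-fold and 90.9% of 4-fold changes, and 5.6% of its calls were false. For the mean of 6 days it recovered 74.6%, 100% and 97%, and 6.7% of its calls were false. The older quasi-likelihood form of edgeR gave 31.6% and 17.3% false calls and was kept as an alternative only. The test of change over days called 1 of 71763 models that had no simulated change.

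Gene lists were fixed before the data were examined, by words in the deposited names and descriptions. They covered jasmonate synthesis, jasmonate response, abscisic acid synthesis, catabolism and signalling, late embryogenesis abundant and dehydrin proteins, sucrose cleavage, sugar transport, trehalose metabolism, starch synthesis, starch breakdown, genes linked to sugar starvation, photosynthesis, cell division, histones, cytosolic ribosomal proteins, MADS-box factors, auxin, cytokinin, gibberellin, ethylene, heat shock proteins, defence, secondary wall and vascular tissue, anther and pollen, meiosis, pistil and ovule, cuticle and epidermis, programmed cell death and autophagy, peroxidases and other antioxidant enzymes, flowering time, and transposon-related genes. The jasmonate, abscisic acid and sugar lists follow the title of the series and are not independent of the study. A list matched by words holds genes of mixed function. Lists of at least 5 members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. The rotation test fry, which asks whether the genes of a list move 1 way without comparing them with other genes, was run beside it.

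Named genes followed a rule also fixed before the data were examined. For the mean of 6 days it took the 10 largest differences in each direction among called genes with the same sign at all 6 days, a mean FPKM of at least 1 and a description. It took the 3 largest in each direction for each day with non-overlapping groups, the 6 smallest p-values for the change over days, the 8 largest in each direction for day 27 against day 6, and the member of smallest p in each direction of each list. In the choices by largest difference, only the largest of the genes sharing a description was taken, so copies with equal descriptions were passed over. The rule gave 141 results in 137 genes. Any other gene named is said to have been chosen after its values were seen.

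Alternatives fixed before the data were examined were median-of-ratios scaling, quantile normalization, log2(FPKM + 0.1), no filter, a filter of FPKM of at least 1 in at least 17 libraries, library weights, a spread without a mean trend, a block for replicate number within day, only the libraries of a day, an estimated correlation for the lists, and leaving out each library. Alternatives added after the values were seen were limma on log2(FPKM + 1), DESeq2 1.42.0, counts divided by 4, the older quasi-likelihood form, leaving out day 9, leaving out day 27, and central libraries interpolated to the time that best matched the basal ones. Replicates were not stated to be separate plants, so each p-value measures a difference against the spread between these samples.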

Results

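Messenger RNA levels were measured by RNA sequencing in basal and central spikelets of wheat ears over 6 days of sampling between day 6 and day 27 after the terminal spikelet stage. There were 17 basal and 17 central libraries, 3 for each position and day except 2 for basal day 15 and 2 for central day 21. Library totals ran from 95144712 estimated counts (basal day 21 replicate 1) to 126139684 (basal day 6 replicate 3). Between 49060 and 55909 gene models reached an FPKM of 1 in a library, and the 10 most abundant models took 0.92 to 2.1% of the counts. The first principal component of the 34 libraries held 51.7% of the variance and followed the day of sampling, and the second held 20.3%. Over 25389 genes, the basal day 9 libraries matched best the day 6.75 on the course of the central libraries, and the basal day 15 libraries matched day 13. Differences below are basal minus central, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

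**Figure D1:**
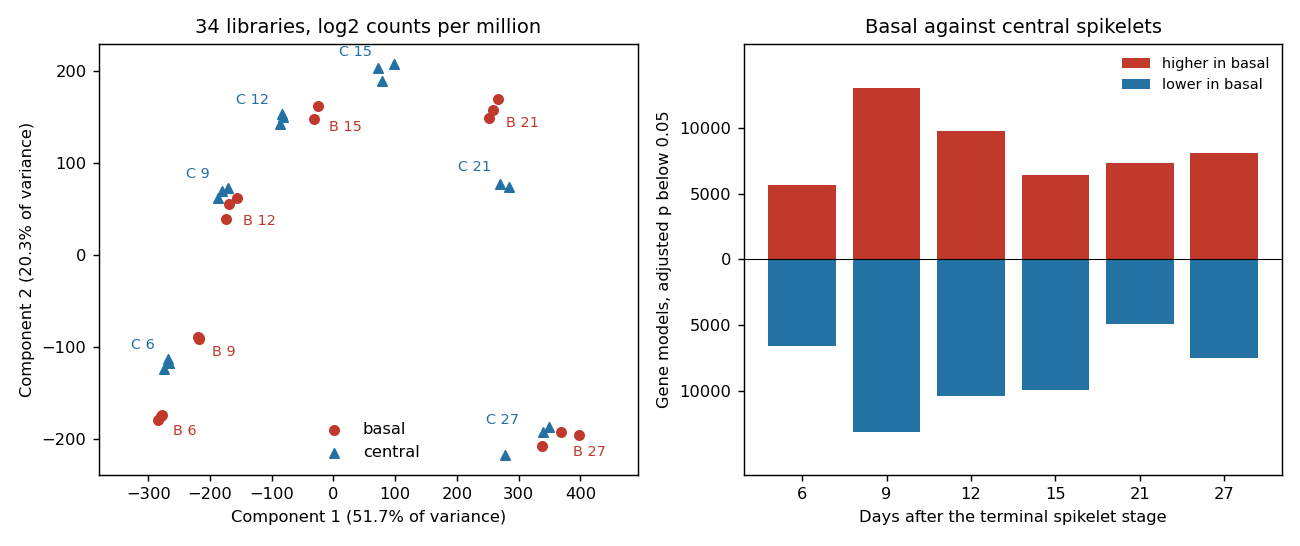
Left, the 34 libraries on the first 2 principal components of log2 CPM, the counts scaled for library size (51.7% and 20.3% of variance), with basal (B, circles) and central (C, triangles) groups named by day. Right, bars show the gene models higher (up) and lower (down) in basal spikelets at each day, with 13018 higher and 13111 lower at day 9 and 7347 higher and 4953 lower at day 21.

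The design asked how basal and central spikelets differ in gene expression, and the mean of the 6 daily differences covers the whole course. HOX12, a homeobox-leucine zipper transcription factor (TraesCS4A03G0078800, chromosome 4A from 34014609 to 34016092), was 6.94-fold higher in basal spikelets (log2 difference 2.79 ± 0.08 SE, adjusted p = 3.53e-19). Its level at day 9 was 49.7 ± 3.5 FPKM in basal and 1.41 ± 0.22 FPKM in central spikelets (SD, n = 3 each). A dormancy-associated protein 1-like gene, of a family abundant in resting buds (TraesCS4D03G0130800, chromosome 4D from 45097463 to 45100876), was 5.36-fold higher (log2 difference 2.42 ± 0.07, adjusted p = 3.53e-19), at 182 ± 29 against 26.2 ± 0.42 FPKM on day 12. An amidase 1-like gene (TraesCS5B03G0247200LC) averaged 2.15 FPKM over the 17 basal and 0.168 FPKM over the 17 central libraries (adjusted p = 1.01e-12). On the lower side, the subtilisin-like protease gene SBT3.9 (TraesCS5D03G0110800, chromosome 5D from 43487244 to 43492264) averaged 0.652 FPKM in basal and 1.76 FPKM in central libraries, a 5.33-fold lower fitted level (adjusted p = 2.83e-11). Stilbene synthase 4 (TraesCS1A03G0432700), annotated as an enzyme of phenolic synthesis, averaged 2.81 against 12.4 FPKM (log2 difference -2.44 ± 0.37, adjusted p = 5.42e-06). Among the 20 genes the naming rule took here, 3 small heat shock protein genes were higher. In the heat shock list another small heat shock gene (TraesCS6B03G0268600) was lower by a fitted log2 difference of -2.48 ± 0.31. In 1 of its groups it stood at 0, so the size of that difference is uncertain. In all, 24122 of 71963 models (33.5%) passed the test, 11535 higher and 12587 lower in basal spikelets, with 739 and 1574 of them differing more than 2-fold. On log2(FPKM + 0.1) there were 10281 higher and 16760 lower, a higher share of 38% in place of 47.8%. The calls of 5 named genes ended (adjusted p = 1) when a single library was left out, since a group then stood at or near 0: the small heat shock gene TraesCS6D03G0379900 without basal day 6 replicate 2, SPIRAL1-like 4 (TraesCS2B03G1056400) and glutathione S-transferase 1 (TraesCS3D03G0279900) without central day 6 replicate 1, a chloroplast dnaJ 11-like gene (TraesCS7D03G1220000) without basal day 9 replicate 2, and the small heat shock gene TraesCS2A03G0776900 without basal day 15 replicate 2.

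**Figure D2:**
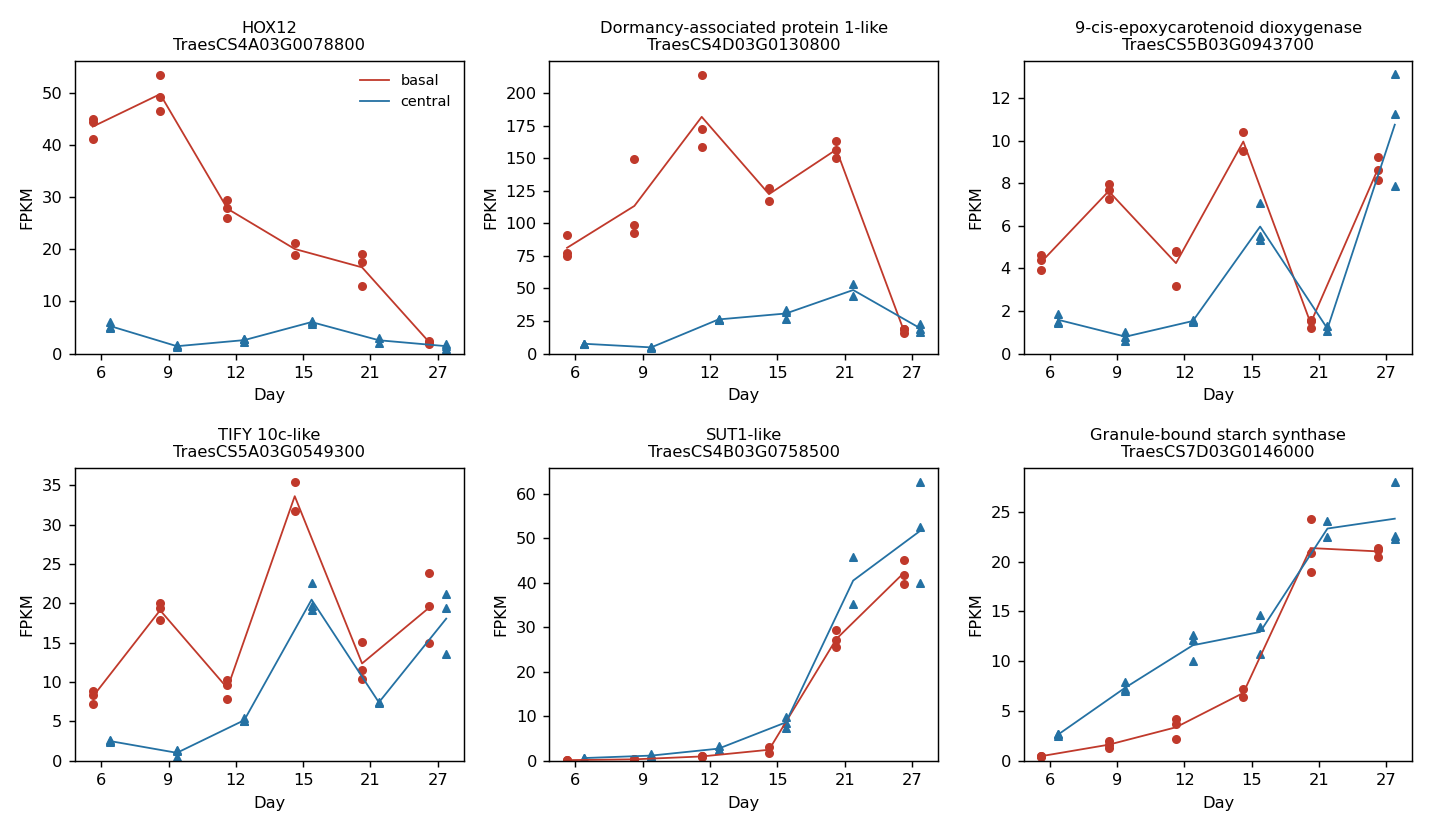
FPKM per library by day for HOX12, a dormancy-associated protein 1-like gene, a 9-cis-epoxycarotenoid dioxygenase, TIFY 10c-like, SUT1-like and granule-bound starch synthase, with basal libraries as circles, central libraries as triangles and lines through group means. HOX12 was at 2.15 ± 0.33 FPKM (basal) and 1.42 ± 0.51 FPKM (central) on day 27, and SUT1-like was at 2.48 ± 0.97 (basal) and 8.63 ± 1.3 FPKM (central) on day 15.

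Jasmonate and abscisic acid genes were the first subject of the series title, so these lists are not independent of the study. The jasmonate response list, which holds the TIFY repressors of the pathway, had 40 members higher, 3 lower and 25 not called in the mean of 6 days (40 and 3 adjusted over the list alone). Its camera test gave adjusted p = 4.06e-07, and adjusted p = 0.208 with an estimated correlation. The list's median log2 difference was 1.31 on day 9, when genes of the plant clock differed too, and 0.08 to 0.24 on the other days. TIFY 10c-like (TraesCS5A03G0549300) was 2.67-fold higher in basal spikelets (log2 difference 1.42 ± 0.09, adjusted p = 3.83e-12). It stood at 19.1 ± 1.1 against 1.01 ± 0.48 FPKM on day 9, but at 14.96 to 23.85 against 13.58 to 21.19 FPKM on day 27. The jasmonate-conjugating enzyme gene JAR1 (TraesCS1B03G1234700) was lower by a log2 difference of -0.24 ± 0.06, a call that ended without day 27 (adjusted p = 0.083). Of 74 jasmonate synthesis genes, 26 were higher, 8 lower and 40 not called (26 and 10 adjusted over the list alone), and the list was not called (adjusted p = 0.075). With no filter it was called (adjusted p = 0.0124), as with the stricter filter (adjusted p = 0.0015) and without basal day 6 replicate 2 (0.0452), basal day 12 replicate 1 (0.0445), basal day 27 replicate 2 (0.0406) or central day 27 replicate 3 (0.0333). An allene oxide synthase 4-like gene, for an early step of jasmonate synthesis (TraesCS6D03G0385700), was 1.81-fold higher, at 6.25 ± 0.48 against 2.19 ± 0.13 FPKM on day 9. The 12-oxophytodienoate reductase 2 gene (TraesCS7A03G0410400) was 2.71-fold lower, at 1.9 ± 0.19 FPKM in central and 0.555 ± 0.13 FPKM in basal spikelets on day 15.

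Among abscisic acid synthesis genes, 7 of 18 were higher and 6 lower (8 and 7 adjusted over the list alone). The list's adjusted p was 0.0471, and it was 0.494 with an estimated correlation. Its call ended in 11 of 34 fits that left out 1 library (adjusted p = 0.0508 to 0.174) and under 9 of 14 other alternatives. A 9-cis-epoxycarotenoid dioxygenase gene, for the rate-limiting step of abscisic acid synthesis (TraesCS5B03G0943700, chromosome 5B from 557004391 to 557006844), was 2.26-fold higher (log2 difference 1.17 ± 0.08, adjusted p = 1.39e-11) and stood at 7.63 ± 0.35 against 0.793 ± 0.2 FPKM on day 9. Its log2 difference was 3.27 on day 9, but 0.42 on day 21 and -0.22 on day 27. Zeaxanthin epoxidase (TraesCS4A03G0510900), which acts earlier in the same pathway, was lower by a log2 difference of -0.58 ± 0.11 (adjusted p = 8.59e-05). Of the 6 genes for abscisic acid 8'-hydroxylase, the main enzyme of its breakdown, 4 were lower and 0 higher (4 and 0 adjusted over the list alone). The abscisic acid catabolism list had adjusted p = 0.00453, and adjusted p = 0.208 with an estimated correlation or 0.063 on log2(FPKM + 1). The hydroxylase gene TraesCS6A03G0725000 was at 0.937 ± 0.14 FPKM in basal and 4.09 ± 0.12 FPKM in central spikelets on day 9, and TraesCS5A03G0601100 was not called in the mean of 6 days (adjusted p = 0.293). The latter was called higher after quantile normalization (log2 difference 0.4, adjusted p = 0.0486) and with limma on log2(FPKM + 1) (0.24, adjusted p = 0.0195). Abscisic acid signalling genes were higher in 8 and lower in 6 of 36 cases (9 and 6 adjusted over the list alone). The abscisic acid signalling list had adjusted p = 0.0215, and adjusted p = 0.274 with an estimated correlation or 0.058 with the stricter filter. In that list the receptor gene PYL9-like (TraesCS1D03G0303200) was 1.36-fold higher, and an abscisic stress-ripening gene (TraesCS4D03G0217900) had a log2 difference of -0.50 ± 0.05, which was not called without day 9 (adjusted p = 0.0979). Late embryogenesis abundant and dehydrin genes, which encode proteins of drying seeds and water-stressed tissue, were higher in 26 and lower in 3 of 55 cases (28 and 3 adjusted over the list alone). The late embryogenesis abundant and dehydrin list had adjusted p = 1.79e-07, and adjusted p = 0.073 with an estimated correlation.

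Sugar genes followed, also lists that are not independent of the study. Sucrose cleavage genes, for sucrose synthases and invertases, were lower in 30 and higher in 4 of 55 cases (31 and 5 adjusted over the list alone), and this list was called with the preset (adjusted p = 4.89e-06) and with the estimated correlation (adjusted p = 0.0437). Sucrose synthase 1 (TraesCS7D03G0082900, chromosome 7D from 19563079 to 19568787) was 1.7-fold lower in the mean of 6 days (adjusted p = 3.84e-11), with 16.7 ± 0.54 FPKM in basal and 67.2 ± 1.9 FPKM in central spikelets on day 12, and with the opposite order on day 21, 172 ± 6.8 against 102 ± 17 FPKM. Sucrose synthase 4 (TraesCS4B03G0471600) was 1.88-fold higher. In the sugar transport list 48 of 135 genes were lower, 12 higher and 75 not called (49 and 12 adjusted over the list alone). The sugar transport list had adjusted p = 4.06e-07, and adjusted p = 0.0527 with an estimated correlation. The sucrose transporter gene SUT1-like (TraesCS4B03G0758500, chromosome 4B from 570563508 to 570568910) was 2.47-fold lower (log2 difference -1.30 ± 0.11, adjusted p = 7.25e-10), and the ERD6-like 4 sugar transporter gene (TraesCS4B03G0883200) was 3.15-fold higher (adjusted p = 1.53e-13).

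Starch synthesis genes were lower in 30 and higher in 2 of 61 cases (30 and 3 adjusted over the list alone). The starch synthesis list had adjusted p = 4.13e-06, and adjusted p = 0.208 with an estimated correlation. Granule-bound starch synthase, which makes amylose (TraesCS7D03G0146000), was 2.39-fold lower (log2 difference -1.26 ± 0.08, adjusted p = 9.3e-13). Of 37 starch breakdown genes 13 were lower and 5 higher (13 and 6 adjusted over the list alone). The starch breakdown list had adjusted p = 0.044, and adjusted p = 0.276 with an estimated correlation. It was not called with library weights (0.0626), with the replicate block (0.0573) or in 8 of 34 fits that left out 1 library (0.0515 to 0.0717). Trehalose metabolism genes, which make and remove the sugar signal trehalose 6-phosphate, were higher in 16 and lower in 8 of 41 cases (19 and 10 adjusted over the list alone). The trehalose list had adjusted p = 0.00453, and adjusted p = 0.13 with an estimated correlation or 0.11 without day 9. Trehalose-phosphate synthase 11 (TraesCS6A03G0903100) was 2.52-fold higher (adjusted p = 4.3e-16), while a trehalose-phosphate synthase 1-like gene (TraesCS1A03G0837600) was 2.13-fold lower (adjusted p = 2.34e-08). The sugar starvation list had 11 of 40 members higher and 3 lower (11 and 3 adjusted over the list alone). The sugar starvation list had adjusted p = 0.0177, and adjusted p = 0.204 with an estimated correlation. Its test pointed up although its median (-0.01, or 0 with groups at 0 at their bound) and mean (-0.01) log2 differences were not above 0. Among its higher members were 3 dormancy-associated genes, whereas an asparagine synthetase gene (TraesCS5B03G0418800) was lower by a log2 difference of -0.53 ± 0.06.

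**Figure D3:**
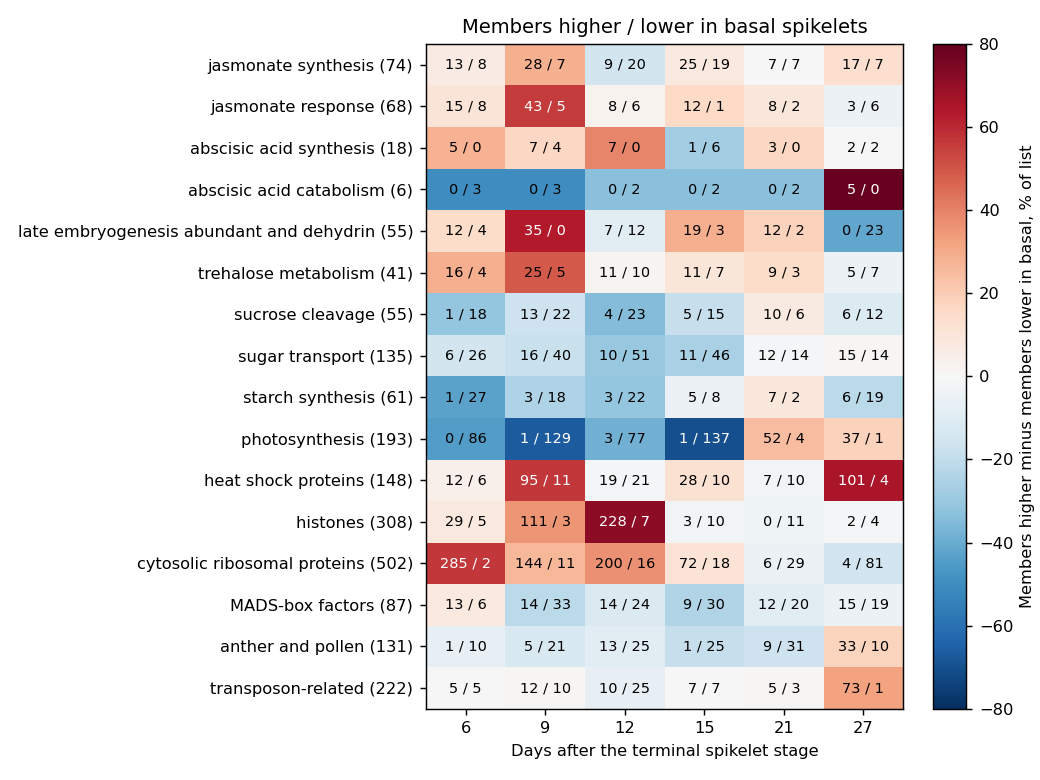
Members higher and lower in basal spikelets for 16 gene lists (vertical axis, with list sizes) at each day (horizontal axis), with colour for members higher minus members lower in percent of the list. Photosynthesis genes went from 0 higher and 86 lower on day 6 to 52 higher and 4 lower on day 21, and heat shock protein genes were higher in 95 cases on day 9 and 101 on day 27; the histone counts of day 6 and the starch synthesis counts of days 15 and 21 changed direction under another scaling.

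Photosynthesis genes were lower in 121 and higher in 1 of 193 cases in the mean of 6 days (128 and 1 adjusted over the list alone). The photosynthesis list had adjusted p = 7.66e-20, and adjusted p = 0.204 with an estimated correlation. A light-harvesting chlorophyll-binding protein gene of photosystem II (TraesCS6D03G0175200) was 1.97-fold lower, at 4.4 ± 0.35 against 64 ± 3.2 FPKM on day 9 and at 68.5 ± 4.4 against 32.5 ± 0.064 FPKM on day 21. Heat shock protein genes, for chaperones of misfolded proteins, were higher in 70 and lower in 12 of 148 cases (70 and 14 adjusted over the list alone), and both camera tests called the list (adjusted p = 7e-18, and adjusted p = 0.00149 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 201 and lower in 17 of 502 cases (213 and 18 adjusted over the list alone). The ribosomal protein list had adjusted p = 6.93e-09, and adjusted p = 0.399 with an estimated correlation. Histone genes were higher in 68 and lower in 4 of 308 cases (46 and 4 adjusted over the list alone). The histone list had adjusted p = 3.37e-06, and adjusted p = 0.544 with an estimated correlation. Of 157 cell division genes 27 were higher and 9 lower (26 and 7 adjusted over the list alone). The cell division list had adjusted p = 0.044, and adjusted p = 0.654 with an estimated correlation. That call also ended without day 9 (adjusted p = 0.474), with the stricter filter (0.165), after quantile normalization (0.105) and in 15 of 34 fits that left out 1 library (0.0513 to 0.16). MADS-box genes, for floral organ and flowering regulators, were lower in 40 and higher in 20 of 87 cases (43 and 20 adjusted over the list alone). The MADS-box list had adjusted p = 0.00452, and adjusted p = 0.238 with an estimated correlation. A MADS-box 1-like gene (TraesCS4D03G0590000) was 2.6-fold lower (adjusted p = 8e-15) and was called lower at all 6 days, and MADS56 (TraesCS1A03G0533300) was 1.98-fold higher (adjusted p = 5.78e-13) and was called higher at all 6 days.

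The lists for vegetative, vascular and floral tissues were counted because whole spikelets hold all of them. Secondary wall and vascular genes were lower in 91 and higher in 21 of 215 cases (98 and 22 adjusted over the list alone). The secondary wall list had adjusted p = 1.02e-06, and adjusted p = 0.183 with an estimated correlation. Cuticle and epidermis genes were lower in 85 and higher in 21 of 329 cases (84 and 21 adjusted over the list alone). The cuticle list had adjusted p = 7.65e-06, and adjusted p = 0.183 with an estimated correlation. Anther and pollen genes were lower in 17 and higher in 3 of 131 cases (14 and 3 adjusted over the list alone). The anther and pollen list had adjusted p = 2.95e-05, and adjusted p = 0.208 with an estimated correlation. Peroxidases and other antioxidant enzymes were lower in 73 and higher in 20 of 247 cases (73 and 22 adjusted over the list alone). The antioxidant enzyme list had adjusted p = 9.05e-05, and adjusted p = 0.204 with an estimated correlation. Meiosis genes were lower in 10 and higher in 3 of 60 cases (7 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.538). Its median was at 0.00 while its mean (-0.03) and its test pointed down. The pistil and ovule list had 3 members, all lower, and was too small to test.

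The remaining lists covered other hormones, defence, flowering time, cell death and transposons. Ethylene genes were higher in 65 and lower in 23 of 202 cases (68 and 25 adjusted over the list alone). The ethylene list had adjusted p = 0.00264, and adjusted p = 0.238 with an estimated correlation. Gibberellin genes were higher in 12 and lower in 4 of 34 cases (12 and 4 adjusted over the list alone). The gibberellin list had adjusted p = 0.0393, and adjusted p = 0.415 with an estimated correlation. Without day 9 (0.68), with library weights (0.0807), with the replicate block (0.0652) and in 4 of 34 fits that left out 1 library (0.0526 to 0.0756) it was not called. The gibberellin receptor gene GID1-like (TraesCS1D03G0613500) was 1.95-fold higher. Auxin genes were lower in 60 and higher in 31 of 267 cases, with equal counts adjusted over the list alone, and the list was not called (adjusted p = 0.075) except with no filter (0.0408), with the stricter filter (0.0437) or without day 9 (0.0419). Cytokinin genes were higher in 26 and lower in 25 of 100 cases (27 and 26 adjusted over the list alone; adjusted p = 0.301), a balance that turned to 23 and 25 with median-of-ratios scaling. The cytokinin-activating enzyme gene LOGL10 (TraesCS1B03G0512300) was 2.9-fold higher (adjusted p = 3.69e-12). Defence genes were higher in 53 and lower in 41 of 272 cases, with equal counts adjusted over the list alone. The defence list was not called (adjusted p = 0.181) except with no filter (0.0415) or the stricter filter (0.00601). Its members were higher in 58 and lower in 70 cases on log2(FPKM + 0.1), and the mean log2 difference (-0.05) was opposite in sign to the median (0.05) and the test. A Bowman-Birk trypsin inhibitor gene of that list (TraesCS3D03G0061500) was 4.67-fold higher (adjusted p = 2.17e-14). Flowering time genes were higher in 24 and lower in 9 of 62 cases, with equal counts adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.132 with an estimated correlation or 0.09 without day 9), and their mean (-0.05) was opposite in sign to their median (0.10) and the test. Programmed cell death and autophagy genes were higher in 14 and lower in 16 of 96 cases, with equal counts adjusted over the list alone (adjusted p = 0.653). Transposon-related genes were higher in 26 and lower in 14 of 222 cases (23 and 10 adjusted over the list alone). The transposon list had adjusted p = 0.044, and adjusted p = 0.438 with an estimated correlation; without day 27 that list pointed down (adjusted p = 0.572). Its call ended too with the stricter filter (0.962), library weights (0.227), the replicate block (0.0648) and in 9 of 34 fits that left out 1 library (0.0504 to 0.168). Of 31 lists tested, 25 were called with the preset correlation, 14 higher and 11 lower, and 2 with an estimated correlation. The rotation test fry called 24 lists, 12 higher and 12 lower.

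At day 6 the comparison asked how both positions differed at the start of the series (n = 3 each). Cytosolic ribosomal protein genes were higher in basal spikelets in 285 of 502 cases and lower in 2 (340 and 9 adjusted over the list alone). The ribosomal protein list had adjusted p = 5.7e-26, and adjusted p = 0.189 with an estimated correlation. Photosynthesis genes were lower in 86 and higher in 0 of 193 cases (93 and 1 adjusted over the list alone). The photosynthesis list had adjusted p = 8.84e-18, and adjusted p = 0.189 with an estimated correlation. Starch synthesis genes were lower in 27 and higher in 1 of 61 cases (32 and 2 adjusted over the list alone). The starch synthesis list had adjusted p = 6.09e-13, and adjusted p = 0.0904 with an estimated correlation. Granule-bound starch synthase (TraesCS7D03G0146000) was at 0.467 ± 0.05 FPKM in basal and 2.64 ± 0.13 FPKM in central spikelets (adjusted p = 5.54e-09). Sucrose cleavage genes were lower in 18 and higher in 1 of 55 cases (20 and 4 adjusted over the list alone), and both tests called the list (adjusted p = 2.68e-07, and adjusted p = 0.0279 with an estimated correlation). A beta-glucosidase 5-like gene (TraesCS3D03G0966500) was at 0 in basal libraries and at 0.587 ± 0.051 FPKM in central ones, at least 13.4-fold lower, and a polygalacturonase gene, for an enzyme that cuts pectin (TraesCS5B03G1147600), was at least 4.36-fold lower. In central libraries a dehydrin DHN3-like gene (TraesCS6D03G0773900) was at 0 and in basal ones at 0.263 ± 0.12 FPKM, at least 2.63-fold higher. The test called 12309 models, 5692 higher and 6617 lower. On log2(FPKM + 0.1) the higher share was 27.7% in place of 46.2%, and with library weights 20242 models were called. The call of the SWEET6a-like sugar transporter gene (TraesCS7D03G1231100; 0 in basal, 0.34 ± 0.26 FPKM in central libraries) ended without central day 6 replicate 1 (adjusted p = 0.0835).

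Day 9 gave 26129 calls, 13018 higher and 13111 lower. Heat shock protein genes were higher in basal spikelets in 95 and lower in 11 of 148 cases (97 and 12 adjusted over the list alone), and both tests called the list (adjusted p = 1.39e-23, and adjusted p = 0.000241 with an estimated correlation). Heat shock protein 90 (TraesCS2A03G0066600) was at 27.9 ± 3.3 FPKM in basal and 1.16 ± 0.12 FPKM in central spikelets (log2 difference 4.59 ± 0.16, adjusted p = 6.01e-18, n = 3 each). Late embryogenesis abundant and dehydrin genes were higher in 35 and lower in 0 of 55 cases (37 and 0 adjusted over the list alone). The late embryogenesis abundant and dehydrin list had adjusted p = 2.21e-13, and adjusted p = 0.00812 with an estimated correlation. Trehalose metabolism genes were higher in 25 and lower in 5 of 41 cases (25 and 6 adjusted over the list alone). The trehalose list had adjusted p = 8.85e-07, and adjusted p = 0.00466 with an estimated correlation. Jasmonate response genes were higher in 43 and lower in 5 of 68 cases (45 and 6 adjusted over the list alone, not independent of the study). The jasmonate response list had adjusted p = 4.32e-12, and adjusted p = 0.181 with an estimated correlation. Photosynthesis genes were lower in 129 and higher in 1 of 193 cases (136 and 1 adjusted over the list alone). The photosynthesis list had adjusted p = 2.05e-24, and adjusted p = 0.181 with an estimated correlation. A 9-lipoxygenase 2-like gene, for an enzyme that oxidizes linoleate (TraesCS5A03G0907300), was at 4.53 ± 0.6 FPKM in basal and at 0 in central libraries, at least 133-fold higher. C-Ph1-5D (TraesCS5D03G0608100) was at 0 in basal and at 1.92 ± 0.4 FPKM in central libraries, at least 19.3-fold lower. In the libraries of that day, 4 of 4 genes of LHY, a clock regulator with its peak near dawn, were lower in basal spikelets (median log2 difference -3.09). GIGANTEA and pseudo-response regulators peak later in the day, and 11 of 11 genes described as GIGANTEA, APRR3, PRR73 or PRR95 were higher (median 1.19). These clock genes were chosen after values had been seen. Genes described only as pseudo-response regulator were left out, so the 11 are a part of that family. A defensin gene (TraesCS1B03G0036700) was at 0 in basal and at 17.4 ± 2.7 FPKM in central libraries, at least 108-fold lower (adjusted p = 0.0232). Its call ended without basal day 9 replicate 1 (adjusted p = 0.0574), replicate 2 (0.0603) or replicate 3 (0.0634). It also ended with the replicate block (0.0871), with a spread without a mean trend (0.0587) and with the older quasi-likelihood form (0.0589).

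**Figure D4:**
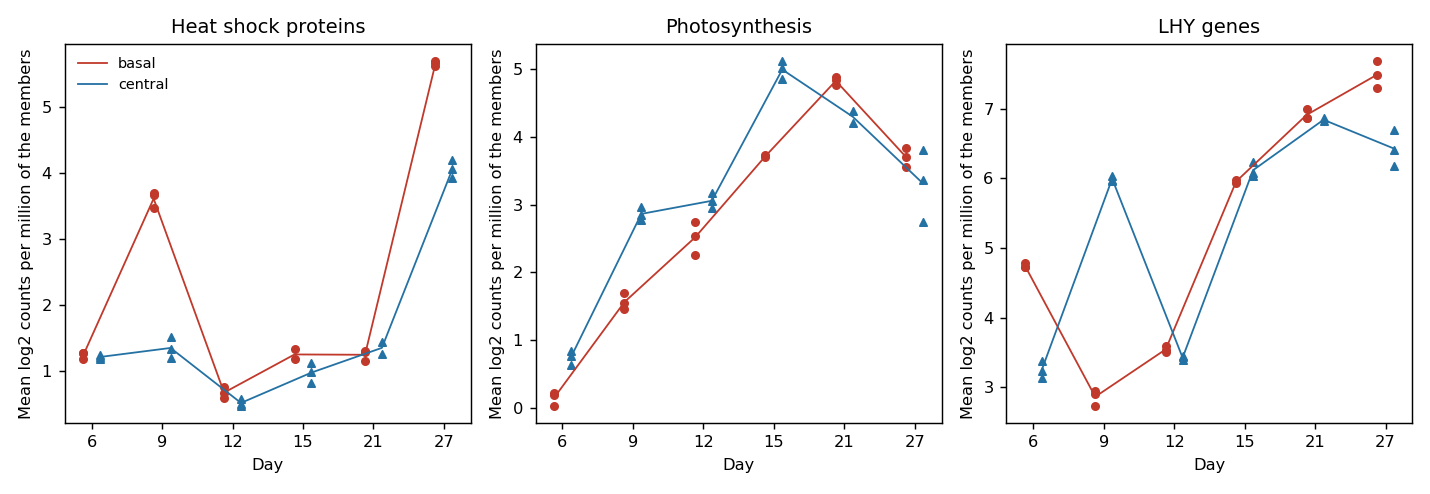
Mean log2 CPM (counts scaled for library size) per library of the heat shock protein genes, the photosynthesis genes and the LHY genes by day, with basal libraries as circles, central libraries as triangles and lines through group means. At day 9 the 4 LHY genes had a median log2 difference of -3.09, and heat shock genes were higher in basal spikelets in 95 cases on day 9 and 101 on day 27.

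By day 12 histone genes were higher in basal spikelets in 228 and lower in 7 of 308 cases (244 and 7 adjusted over the list alone). The histone list had adjusted p = 1.26e-23, and adjusted p = 0.519 with an estimated correlation. Cell division genes were higher in 63 and lower in 4 of 157 cases (69 and 5 adjusted over the list alone). The cell division list had adjusted p = 9.95e-07, and adjusted p = 0.519 with an estimated correlation. Cytosolic ribosomal protein genes were higher in 200 and lower in 16 of 502 cases (215 and 18 adjusted over the list alone). The ribosomal protein list had adjusted p = 4.41e-13, and adjusted p = 0.519 with an estimated correlation. Sugar transport genes were lower in 51 and higher in 10 of 135 cases (56 and 12 adjusted over the list alone, not independent of the study). The sugar transport list had adjusted p = 6.55e-07, and adjusted p = 0.0834 with an estimated correlation. Secondary wall and vascular genes were lower in 75 and higher in 16 of 215 cases (79 and 22 adjusted over the list alone). The secondary wall list had adjusted p = 6.55e-07, and adjusted p = 0.432 with an estimated correlation. Cellulose synthase A4, for a subunit of the secondary wall enzyme (TraesCS3D03G0666000), was at 0.353 ± 0.032 FPKM in basal and 3.94 ± 0.45 FPKM in central spikelets (log2 difference -3.50 ± 0.18, adjusted p = 1.15e-13, n = 3 each). A GDSL esterase gene (TraesCS7B03G1226300) was at 0 in basal and at 4.37 ± 1.2 FPKM in central libraries, at least 59.6-fold lower, and a cytosolic sulfotransferase 8-like gene (TraesCS2D03G0687600) was at 0.413 ± 0.087 FPKM in basal and at 0 in central libraries, at least 4.67-fold higher. In total 20198 models were called, 9775 higher and 10423 lower. The balance depended on the scaling, with 8379 higher and 11739 lower by median-of-ratios, 10574 and 9737 on log2(FPKM + 0.1), and 11706 and 9495 on log2(FPKM + 1).

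For day 15 there were 2 basal and 3 central libraries. Photosynthesis genes were lower in basal spikelets in 137 and higher in 1 of 193 cases (145 and 1 adjusted over the list alone). The photosynthesis list had adjusted p = 1.79e-36, and adjusted p = 0.363 with an estimated correlation. MADS-box genes were lower in 30 and higher in 9 of 87 cases (35 and 10 adjusted over the list alone). The MADS-box list had adjusted p = 0.000656, and adjusted p = 0.368 with an estimated correlation. The MADS-box 1-like gene (TraesCS4D03G0590000) was at 8.38 ± 0.26 FPKM in basal and 16.7 ± 0.47 FPKM in central spikelets (adjusted p = 2.69e-05). The tricetin O-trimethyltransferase gene (TraesCS3A03G1266900), annotated to methylate a flavone, was at 13.2 ± 0.62 against 81.2 ± 1.1 FPKM (adjusted p = 3.98e-11). An alpha-humulene synthase-like gene (TraesCS2D03G0008900) was at 0 in basal and at 3.07 ± 1 FPKM in central libraries, at least 59-fold lower, and an aquaporin gene of the PIP2 group (TraesCS5A03G0802100) was at least 34.1-fold lower. Higher genes included a subtilisin-chymotrypsin inhibitor-2A gene (TraesCS3A03G0207800), at 1.08 ± 0.057 FPKM in basal and 0 in central libraries, at least 5.26-fold higher. The test called 16345 models, 6396 higher and 9949 lower, and the higher share of 39.1% became 56.7% on log2(FPKM + 0.1) and 51% after quantile normalization. With 1 basal library left out, 9604 models were called without basal day 15 replicate 1 and 10776 without replicate 2. A dehydrin DHN3 gene (TraesCS6B03G1083500LC; 1.69 ± 2 FPKM against 0) and a histone H4-like gene (TraesCS5B03G0875800; 14.6 ± 20 against 0.07 ± 0.03 FPKM) were called, but not without basal day 15 replicate 1 (adjusted p = 0.469 and adjusted p = 0.907), and the dehydrin call also ended without central day 15 replicate 2 (0.05) or replicate 3 (0.0527).

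On day 21, with 3 basal and 2 central libraries, photosynthesis genes were higher in basal spikelets in 52 and lower in 4 of 193 cases (69 and 4 adjusted over the list alone). The photosynthesis list had adjusted p = 4.02e-11, and adjusted p = 0.592 with an estimated correlation. Anther and pollen genes were lower in 31 and higher in 9 of 131 cases (34 and 9 adjusted over the list alone). The anther and pollen list had adjusted p = 1.94e-10, and adjusted p = 0.18 with an estimated correlation. A group 11 grass pollen allergen gene (TraesCS1B03G1194200) was at 0 in basal and at 4.38 ± 1.7 FPKM in central libraries, at least 23.4-fold lower, and the actin-depolymerizing factor 6 gene (TraesCS2A03G0985300) was at 0 and 2.7 ± 0.81 FPKM, at least 17.2-fold lower. On day 27 the latter gene stood at 20.9 ± 8.6 FPKM in basal and 22.7 ± 4.9 FPKM in central libraries. Cell division genes were lower in 24 and higher in 4 of 157 cases (33 and 4 adjusted over the list alone). The cell division list had adjusted p = 4.8e-08, and adjusted p = 0.592 with an estimated correlation. Gibberellin genes were lower in 11 and higher in 0 of 34 cases (12 and 0 adjusted over the list alone). The gibberellin list had adjusted p = 0.00117, and adjusted p = 0.583 with an estimated correlation. Sucrose synthase 1 (TraesCS7D03G0082900) was higher, by a log2 difference of 0.89 ± 0.14 (adjusted p = 8.97e-05). The test called 12300 models, 7347 higher and 4953 lower, and the higher share of 59.7% became 31.1% on log2(FPKM + 0.1), where the median of all genes lay at -0.13, and 49.4% after quantile normalization. Without central day 21 replicate 1 there were 7021 calls, and 5987 without replicate 2, and the replicate block gave 7893. DESeq2 did not call the pollen allergen (adjusted p = 0.182) or the actin factor (adjusted p = 0.221), and the 9-lipoxygenase 2-like gene (TraesCS5A03G0907300; 1.21 ± 0.62 FPKM in basal, 0 in central libraries) was not called without central day 21 replicate 2 (adjusted p = 0.0567).

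Heat shock protein genes were again higher in basal spikelets on day 27, in 101 and lower in 4 of 148 cases (103 and 7 adjusted over the list alone). The heat shock protein list had adjusted p = 5.05e-34, and adjusted p = 1.48e-05 with an estimated correlation. Heat shock protein 90 (TraesCS2A03G0066600) was at 234 ± 45 FPKM in basal and 49.4 ± 2.9 FPKM in central libraries (log2 difference 2.35 ± 0.14, adjusted p = 3.98e-13, n = 3 each). Transposon-related genes were higher in 73 and lower in 1 of 222 cases (76 and 1 adjusted over the list alone). The transposon list had adjusted p = 2.21e-11, and adjusted p = 0.0441 with an estimated correlation. Cytosolic ribosomal protein genes were lower in 81 and higher in 4 of 502 cases (67 and 3 adjusted over the list alone). The ribosomal protein list had adjusted p = 2.9e-07, and adjusted p = 0.815 with an estimated correlation. Late embryogenesis abundant and dehydrin genes were lower in 23 and higher in 0 of 55 cases (26 and 0 adjusted over the list alone). The late embryogenesis abundant and dehydrin list had adjusted p = 0.00151, and adjusted p = 0.406 with an estimated correlation. The abscisic acid 8'-hydroxylase genes were higher in 5 and lower in 0 of 6 cases (5 and 0 adjusted over the list alone, not independent of the study). The abscisic acid catabolism list had adjusted p = 0.000365, and adjusted p = 0.228 with an estimated correlation. Among them, TraesCS5A03G0601100 stood at 10.7 ± 4 against 2.64 ± 0.94 FPKM (adjusted p = 2.43e-06). Anther and pollen genes were higher in 33 and lower in 10 of 131 cases (34 and 12 adjusted over the list alone). The anther and pollen list had adjusted p = 0.00923, and adjusted p = 0.811 with an estimated correlation. HOX12 (TraesCS4A03G0078800) was higher by a log2 difference of 0.69 ± 0.21 (adjusted p = 0.018). Of its copies, chosen after values were seen, TraesCS4B03G0697100 was called lower that day (log2 difference -1.44) and TraesCS4D03G0623900 was not called (-0.44). The dormancy-associated protein 1-like gene (TraesCS4D03G0130800) was at 18 ± 1.7 against 19.3 ± 3.2 FPKM (adjusted p = 0.975). The test called 15597 models, 8122 higher and 7475 lower, and the higher share of 52.1% became 36.4% on log2(FPKM + 0.1). A fit of the libraries of that day alone called 3266 models. Central day 27 replicate 1 stood apart from the other 2 central libraries, at 277.3 on the first principal component against 338.8 and 348.6. Its chi-square per gene was 22.2 and 32.76 against replicates 2 and 3, which had 9.62 between them.

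Whether the difference between positions changed over the days was tested next, and it did for 40768 models. The pseudo-response regulator gene APRR3, of the plant clock (TraesCS4D03G0224500, chromosome 4D from 93788126 to 93794668), was at 17.6 ± 0.6 FPKM in basal and 3.56 ± 0.067 FPKM in central spikelets on day 9, and at 2.79 ± 0.27 against 5.14 ± 0.11 FPKM on day 27 (adjusted p = 3.24e-17 for the change). A MYB-related gene (TraesCS7B03G1286300) went the other way, at 0.783 ± 0.05 against 9.17 ± 0.79 FPKM on day 9 and 17.9 ± 2 against 3.04 ± 0.4 FPKM on day 27 (adjusted p = 3.24e-17). B-box zinc finger 18-like (TraesCS5A03G0769500) was at 8.17 ± 0.19 against 28.4 ± 0.72 FPKM on day 9 and at 15.2 ± 0.11 against 9.74 ± 0.4 FPKM on day 6. Tricetin O-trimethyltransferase (TraesCS3A03G1266900) was lower in basal spikelets on day 15 and higher on day 21, at 213 ± 11 against 131 ± 4 FPKM. Of 50135 models called on at least 1 day, 14213 were higher on some days and lower on others, 7399 of them lower between days 6 and 15 and higher on day 21 or 27, and 4280 the reverse. On all 6 days 41 models were called higher and 27 lower. Days 6 and 9 shared 2748 higher models where 1030 would be shared if the days were independent. Between days 9 and 21, 3378 models were lower on the first and higher on the second, where 1339 would be if independent.

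Changes with time, as the mean of both positions, compared neighbouring days and the ends of the series. A jacalin-related lectin 23-like gene (TraesCSU03G0493000, not placed on a chromosome) was at 0 in basal and 0.02 ± 0.035 FPKM in central spikelets on day 6 and at 678 ± 27 and 402 ± 97 FPKM on day 27 (adjusted p = 3.1e-19). Horcolin, another lectin gene (TraesCS1B03G1250500LC), stood at 489 ± 41 FPKM in basal and 308 ± 100 FPKM in central spikelets on day 27, and a cytochrome P450 72A15-like gene (TraesCS7D03G1041500) at 39.9 ± 6.2 and 51 ± 8.1 FPKM. In the other direction, UDT1-like, named for a rice factor of tapetum development (TraesCS2A03G0452800), was at 2.48 ± 0.51 and 8.32 ± 1.5 FPKM on day 6 and at 0 in both positions on day 27 (adjusted p = 1.17e-15). Peroxidase 40 (TraesCS5A03G0784800) was at 3.18 ± 1 FPKM in basal and 31.3 ± 6.3 FPKM in central spikelets on day 6. The call of a histone H2B.3-like gene (TraesCS3D03G0764500) ended without basal day 6 replicate 1 (adjusted p = 0.117) or central day 6 replicate 3 (adjusted p = 0.308). It also ended with the replicate block (0.0637) and with library weights (0.0952). From day 6 to day 27, 30467 models rose and 27053 fell, with 19644 and 11702 of them changing more than 2-fold. The higher share of 53% became 39.5% after quantile normalization, which put the median of all genes at -0.33 against 0.06 with TMM. Between neighbouring days, 16726 models rose and 17419 fell from day 6 to day 9, 17473 and 13442 from day 9 to 12, 19232 and 15243 from day 12 to 15, 21073 and 21024 from day 15 to 21, and 23405 and 21807 from day 21 to 27. After quantile normalization more models fell than rose in each of these steps, with 14785 rising and 17614 falling from day 6 to 9, 14484 and 15650 from day 9 to 12, 15265 and 20343 from day 12 to 15, 19389 and 22977 from day 15 to 21, and 21897 and 23420 from day 21 to 27. On log2(FPKM + 0.1) the share that rose from day 6 to day 9 was 65.2% in place of 49%, and from day 12 to day 15 it was 42.1% in place of 55.8%.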

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

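The tests of sampling time, the test of basal day 9 against central day 6 and the splits of the libraries were chosen after the result was seen; the test for background reads was written before its value was seen. The difference between basal and central spikelets changed over the 6 days in 40768 models (56.7%) and in 123 of the 137 named genes, by the test of that change itself. The naming rule took genes partly by that test and by large differences, so the named genes are not a separate result. For the lists, each day's difference was tested against the other 5 days with an estimated correlation. Heat shock protein genes departed on day 9 (adjusted p = 0.00406; median log2 difference 1.4 against 0.22 on the other days, or 1.2 and 0.24 with groups at 0 at their bound), and on day 27 (adjusted p = 0.0176; 1.55 against 0.25). The same test passed on day 12 (adjusted p = 0.0238; 0.14 against 0.55), on day 21 (adjusted p = 0.0238; -0.03 against 0.61) and on day 6 (adjusted p = 0.0392; 0.05 against 0.6), but the other days then hold the high days 9 and 27, so these 3 are not separate findings. Trehalose metabolism genes departed on day 9 (adjusted p = 0.0238; 0.57 against -0.06), as did late embryogenesis abundant and dehydrin genes (adjusted p = 0.0436; 2.33 against 0.34, or 1.64 and 0.23 at bounds).

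The heat shock, trehalose and dehydrin genes of day 9 moved together with genes of the plant clock. A lag of basal spikelets in development is argued against for the heat shock list, since basal day 9 stood above central day 6 as well, by a median of 1.23 on the log2 scale with 88 of 148 members higher and 1 lower. A different time of sampling in the day is a candidate explanation that the values allow, because the 4 LHY genes had a median of -3.09 and the 11 GIGANTEA and pseudo-response regulator genes a median of 1.19, each larger than on any other day. Whether the basal spikelets of day 9 were warmer or drier when taken was not tested, and a difference tied to position stays open. On day 6 the LHY genes also differed (median 1.38, 4 of 4 higher), while the GIGANTEA and pseudo-response regulator genes had a median of -0.16, with 3 of 11 lower and 0 higher.

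On day 27, 73 of 222 transposon-related genes and 101 of 148 heat shock protein genes were higher in basal spikelets. Genomic DNA or background reads, spread over the genome, would raise the share of gene models with a count. Its mean was -0.17 percentage points apart (66.92 to 67.15% in basal, 66.78 to 67.55% in central libraries). That met the limit set beforehand against such reads. On each earlier day, however, the share was lower in every basal library, as with 64.06 to 65.27% against 67.54 to 67.8% on day 21. Near-equal shares on day 27 therefore cannot exclude such reads in the basal libraries. A share of counts was also taken over transcript-assembly models, leaving out tested models with an annotated name. Untested models with a name may be among them. That share of counts was higher in each basal library of day 27 (1.62 to 1.705% against 1.493 to 1.517%), the direction such reads would give. It was higher in each basal library of day 12 too (1.741 to 1.886% against 1.572 to 1.6%), when 10 transposon-related genes were higher and 25 lower (list median -0.27). The same was seen on day 15 (1.645 to 1.709% against 1.467 to 1.537%), when the median of that list was 0.12. Another time of sampling cannot be told apart from position on day 27: the GIGANTEA and pseudo-response regulator genes had a median of -0.21 with 6 of 11 lower, and the LHY genes a median of 0.46 with 3 of 4 higher, opposite ways but smaller than on day 9. Position, and a stress of the tissue that may raise both lists, stay open and were not tested.

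Other splits of the libraries were counted for single days with 3 libraries in each group, and for contrasts over several days, which include the groups of 2 of days 15 and 21. On single days the 10 splits of 6 libraries are too few for a share under 0.05: in 1 of the 10 splits, the real one, day 6 called 12309 models and the highest other split 2. The values were 26129 and 1 on day 9, 20198 and 6 on day 12, and 15597 and 7530 on day 27. As single days, days 15 and 21 had a group of 2 and were not split. For the mean of 6 days, 30 splits drawn at random, the real one included, exchanged libraries within days, and 1 of the 30 called as many models, the real one. Chance is argued against there at a share of 1 in 30, the lowest that 30 splits can give, with 24122 models against at most 816 in the others. The same share held for the change over days, with 40768 against at most 3110. These splits also removed the constant difference between positions, so they cannot test the change over days separately.

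For the steps between days, 21 splits per step, drawn the same way, exchanged libraries between the 2 days within a position, and again 1 of the 21, the real one, called as many models. That is the lowest share 21 splits can give, and it was not adjusted over the steps, so chance is not excluded for any single step. The real split called 34145 models for day 9 against day 6 (highest other split 15225). The values were 30915 and 9861 for day 12 against day 9, and 34475 and 25528 for day 15 against day 12. They were 42097 and 25725 for day 21 against day 15, 45212 and 40534 for day 27 against day 21, and 57520 and 46400 for day 27 against day 6.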

How the results depend on the processing

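Tests chosen after the values were seen were limma on log2(FPKM + 1), DESeq2, counts divided by 4, the older quasi-likelihood form, leaving out day 9 or day 27, and the central libraries interpolated in time. Of the counts of called models, 189 of the values under alternatives other than leaving out a library stayed within 1.5 times the reported count and 4 moved. Those were 20242 models at day 6 with library weights, 7893 at day 21 with the replicate block, 3266 at day 27 with the libraries of that day alone, and 2 of 31 lists called with an estimated correlation; the cause was not tested for the first 3. The list of transposon-related genes reversed without day 27 (adjusted p = 0.572). Leaving out each library in turn gave 8481 to 13893 models at day 6, 22119 to 27441 at day 9, 13590 to 21811 at day 12, 9604 to 17696 at day 15, 5987 to 14361 at day 21, 10860 to 17264 at day 27 and 22093 to 25316 for the mean of 6 days. It gave 31604 to 34933 from day 6 to 9, 28030 to 32002 from day 9 to 12, 29597 to 35430 from day 12 to 15, 38295 to 42869 from day 15 to 21, 41706 to 45538 from day 21 to 27, 56324 to 57733 from day 6 to 27, 38074 to 42795 for the change over days, and 21 to 25 lists. The highest count came without central day 27 replicate 1 for days 6, 9, 12, 15 and 21, the mean of 6 days and the 4 steps from day 6 to 21. The values that moved by over 1.5 times were those without a basal day 15 replicate at day 15 (9604 and 10776) and without a central day 21 replicate at day 21 (7021 and 5987), where a group of 2 became a group of 1 whose lone library was taken to vary like the other groups.

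The values showed no pairing of basal with central libraries by replicate number, with correlations of their deviations from -0.11 to 0.126. With so few libraries in a group, these correlations cannot exclude a pairing. The replicate block gave 10250, 24339, 17897, 11069, 7893 and 13392 models for the 6 days in order, 21268 for their mean, 33008 for the change over days and 21 lists. Without day 9 the mean of the remaining days gave 18076 models and 21 lists, and without day 27 it gave 24772 models and 23 lists. Of 141 named gene results, 140 were called and 113 kept their call and direction under every alternative that was run, while 32 values of named genes lost their call and 2 gained it outside the single-library alternatives, and 19 lost it within them. Of the 25 lists called, 2 kept call and direction throughout. Lists not called that gained a call were jasmonate synthesis, auxin and defence with no filter (adjusted p = 0.0124, 0.0408 and 0.0415) and with the stricter filter (0.0015, 0.0437 and 0.00601), auxin without day 9 (0.0419), and jasmonate synthesis without any 1 of 4 libraries (0.0333 to 0.0452). Genes near the floor of 12 counts are those for which depth limits a statement.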

Other observations

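The tests of sampling time were chosen after the result was seen, as were the genes described here; the tests of a lag in development were added after the daily differences had been seen, with their limits written before their own values were seen. Genes linked to the arrest of buds, with 1 class of abscisic acid synthesis genes, were followed as a set of 20. They were the TEOSINTE BRANCHED 1-like, HOX12, HOX14-like, dormancy-associated protein 1 and 9-cis-epoxycarotenoid dioxygenase genes. TEOSINTE BRANCHED 1 of maize restrains the outgrowth of axillary buds. The wheat genes here carry that name by description only, and whether they share its function was not tested. In the mean of 6 days 18 of the 20 were higher in basal spikelets and 1 was lower, with a median log2 difference of 1.43, or 1.36 with groups at 0 taken at their bound. All 7 dioxygenase genes, 3 of 3 HOX12 genes, 3 of 3 dormancy-associated protein 1 genes, 2 of 2 TEOSINTE BRANCHED 1-like genes and 3 of 5 HOX14-like genes were among the higher ones. The abscisic acid synthesis list, which holds the dioxygenases, had 7 of 18 members higher and 6 lower (median 0.02). The set took the higher class of that list and does not stand for abscisic acid genes as a whole. The low-confidence dioxygenase models TraesCS5A03G0075100LC and TraesCS5A03G0075200LC adjoin on chromosome 5A (29449637 to 29451091 and 29451106 to 29451480) and may be parts of the same gene. Many members are copies on related chromosomes, so their counts are not independent. The TEOSINTE BRANCHED 1-like gene TraesCS5D03G0003700 averaged 2.68 FPKM in basal and 0.542 FPKM in central libraries, 4.18-fold higher and called on 4 of 6 days (adjusted p = 1.21e-10), and its copy TraesCS5A03G0003300 averaged 0.728 against 0.0447 FPKM. HOX12 on chromosome 4D (TraesCS4D03G0623900) averaged 26 against 2.22 FPKM, 8.13-fold higher and called on 5 of 6 days (adjusted p = 2.01e-18). By day, 16, 18, 17, 11 and 13 members were higher on days 6, 9, 12, 15 and 21, and on day 27 there were 2 higher and 5 lower with a median of -0.20.

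Each library was also placed on the course of the central groups over 25389 genes, in steps of 0.25 days. The basal libraries of day 6 matched day 6, the first point of that course, so a lag could not be measured on day 6. Basal libraries of days 9, 12, 15, 21 and 27 matched days 6.75, 10.25, 13, 19.75 and 26.33, which are lags of 2.25, 1.75, 2, 1.25 and 0.67 days. The course was made from the central libraries themselves, so their own match to it is no check. In 6334, 7239, 4635, 5646 and 6043 models the basal level of those days lay beyond both the central level of the same day and that of the day sampled before, 24.2%, 35.8%, 28.4%, 45.9% and 38.7% of the called models. Central libraries of days 9, 12, 15 and 21 lay beyond both the day sampled before and the day sampled after in 4020, 2145, 4772 and 10492 models, a wider bracket in time, so the counts are not directly comparable.

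A lag of basal spikelets in development was weighed as a candidate explanation for the bud arrest set. Against central libraries interpolated to the matched time, the median of the set over days 12 to 27 was 152% of its same-day value (1.42 against 0.93), where a lag would have shrunk it, and 17, 17, 11 and 9 of 20 members on days 9, 12, 15 and 21 lay above both the same and the earlier central day. On day 27 0 members lay above both and 3 below both. Under the same matching the difference of some other lists over days 12 to 27 shrank or turned and that of others grew, so growth was not particular to the set. Photosynthesis went from 4 higher and 64 lower to 20 and 8, sugar transport from 10 and 40 to 17 and 20, and cytosolic ribosomal proteins from 31 and 22 to 11 and 143. Cell division went from 13 and 19 to 6 and 57, jasmonate response from 15 and 0 to 40 and 0, late embryogenesis abundant and dehydrin genes from 10 and 9 to 30 and 1, and jasmonate synthesis from 19 and 11 to 36 and 4. For these lists no limit for a lag was set, and it was not tested. Another time of sampling in the day is argued against by a median of 1.01 over the 5 days other than day 9, with medians of 1.67, 1.26 and 1.66 on days 12, 15 and 21, when the LHY genes differed by -0.03, -0.18 and 0.09. The 11 GIGANTEA and pseudo-response regulator genes had medians of -0.16, -0.16 and -0.02 on those days, with 4, 3 and 2 lower and 0, 0 and 1 higher. For all genes the matched comparison called 19463 models, 112.4% of the 17312 of the same days, but central days compared with the line through their own neighbours gave 35288 calls, so curved time courses make calls of their own and a lag cannot be told apart from position for the genome as a whole. A difference tied to position along the ear, as a hypothesis found and tested on the same data, stays open for the set, as do nutrient supply and the share of tissues in a spikelet, which were not tested.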
